A study of Mus musculus with 12 samples.

How the data were processed

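Polyadenylated RNA of hybrid mouse cells (129Sv x Cast/EiJ) had been sequenced as paired-end reads of 100 bp on an Illumina sequencer. The values used were those of 2 embryonic stem (ES) lines, F1-21.6 (XX) and F1-23 (XY), and of 8 clonal neural progenitor (NPC) lines grown from them. The XX clones 129, C2, G4 and E1.2 are replicates 1 to 4 of the XX NPC group, and the XY clones mC3, mE6, mB4 and mG3 are replicates 1 to 4 of the XY NPC group, with 1 library each. 2 repeat libraries, of clones C2 and mC3, were not analysed here. The labels give the XX NPC libraries another name prefix than the ES and XY NPC libraries, so line, sex chromosomes and library set coincide among NPC clones and cannot be told apart. No paired analysis was possible because the numbers of the clones do not pair XX with XY clones, or NPC with ES libraries. Each library set holds NPC clones of 1 line only, so no within-set value of the XX and XY difference can be given. For NPC against ES, the set shared by both ES lines and the XY clones was run as an alternative.

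The table deposited by the authors gives, per gene and library, counts (whole numbers, taken as observations informative for the allele), the share of those counts from 129 (a ratio from 0 to 1, printed here in percent) and FPKM (fragments scaled to transcript length and library size). Per the labels, TopHat 1.4.0, Cufflinks 1.3.0 and SAMtools were used with the mouse build mm9, without a statement of which step made which column. The variant list and whether a read over several variants was counted once are not stated, so a count is not taken as a molecule. The table has 14899 genes, 14415 autosomal and 484 X-linked. 694 names join several genes, 699 are unnamed transcript fragments and 16 were turned into dates. Every gene has at least 11 counts in at least 1 NPC clone, while 1635 genes stay under 11 counts in both ES lines, so genes expressed in ES cells alone are missing. Counts times share were whole to within 0.01 for all autosomal values, but 19.4% of X-linked values were not. Total counts per library ran from 61375911 to 119266777, with a median count per gene from 1011 to 1947. Coordinates are mm9 with starts counted from 1.

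Choices were made before the data were examined, except those named as added later. Not among them were the tests of the 129 share of monoallelic calls, of imprinted imbalance and of list shares of random genes. The same holds for the overlap split by depth, X-linked against autosomal calls, and the interaction of line and cell type. A gene was testable in a library with at least 20 counts. It was called monoallelic where the major allele had at least 85% of the counts and the exact binomial test against equal shares passed a Benjamini-Hochberg (BH) adjusted p of 0.05 within the library. It was called biallelic where the major allele had at most 70%. Random monoallelic genes were autosomal genes testable in at least 6 of the 8 NPC clones, monoallelic in at least 1, and biallelic or monoallelic for the other allele in at least 1 other clone. Fixed-allele genes were monoallelic for the same allele in every testable clone. Heterogeneity of allele shares among the clones was tested per gene by a quasi-likelihood test whose overdispersion follows depth. The planned estimate of overdispersion from clones and their repeats was not used here. Group means were compared by exact two-sided permutation tests over 45 splits (8 against 2, smallest possible p 0.0444) or 70 splits (4 against 4, smallest possible p 0.0286). The overlap between lines was tested by Fisher's exact test on genes testable in at least 3 clones of each line and not of fixed allele. Expression of random monoallelic genes, as mean log2(FPKM + 1) of monoallelic minus biallelic clones, was tested over genes by sign flips with 100000 permutations. The imbalance of the imprinted genes is the mean distance of the 129 share from 50%, doubled so that a single allele gives 100%. Shares of single libraries have exact Clopper-Pearson 95% intervals. Intervals, and floors of 3 counts for a library or group without counts, cover counting error only. Observations in the same read are not independent, so the intervals understate the error.

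Counts summed over alleles were compared with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, BH 0.05), with the line as a covariate for NPC against ES, and without one for XX against XY NPC clones. Interaction of line and cell type was tested in a fit of all 10 libraries. The counts cover only positions that tell the alleles apart, so they depend on the variants in a gene and levels are compared only between libraries. Levels are in CPM, counts scaled to the effective library total. Fold changes against a group without counts are lower bounds against a floor of 3 counts over the group. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with the estimated correlation. They cover pluripotency, neural progenitors and radial glia, neurons, astrocytes, oligodendrocytes, embryonic fibroblasts (feeder cells), endoderm, mesoderm, forebrain patterning, hindbrain and spinal patterning, DNA methylation and Polycomb, the cell cycle, imprinted genes, escape from X inactivation and the Xist locus, housekeeping genes, cadherins and protocadherins, and dominant dosage-sensitive disease genes. A Y-linked list had none of its 8 genes in the table. DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3 were also used.

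Genes are named by a rule. For expression these are up to 4 called members of each list with the largest change (or 2 of the most expressed if none was called), and the 5 largest changes in each direction among genes above the lowest quartile of mean expression whose groups do not overlap. For alleles these are random monoallelic genes of the lists, the 15 with the largest range of shares, up to 20 imprinted genes and the testable escape genes. Some genes that meet it are not reported here. Genes outside the rule are marked as chosen after their values were seen. Tested on simulated data, the random rule recovered 100% of 100 genes made monoallelic in 1 clone, with 8 false calls among 12108 genes. The heterogeneity test recovered 95% with 23 false calls, and without overdispersion it made 10650 false calls. The simulated genes lay close to equal shares, and genes with a standing skew to 1 allele were hardly simulated. These false calls are therefore not an error rate for the real genes. Simulated 4-fold changes were recovered for 72% of genes in NPC against ES and 83% in XX against XY, and 2-fold changes for 19% and 42%. Alternatives tried were other count minimums, allele thresholds, a beta-binomial test, centred shares, thinned counts, genes testable in all libraries, an FPKM minimum, leaving out each library, leaving out clones G4 and E1.2, other normalizations, DESeq2, limma on FPKM, no filter, no covariate, and no X-linked genes.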

Results

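RNA was sequenced from hybrid 129Sv x Cast/EiJ mouse cells, in which reads over strain variants show the allele they came from. The series concerns random monoallelic expression, in which cells of the same type express a gene from 1 allele, and that choice is kept in a clone. There were 2 ES lines (n = 1 library each) and clonal NPC lines grown from them, 4 XX clones and 4 XY clones. Total allele-informative counts were 61375911 in the XX ES line and 65171172 in the XY ES line. They were 66611144, 100631463, 102153897 and 119266777 in XX clones 129, C2, G4 and E1.2, and 91955553, 82161686, 72230497 and 89166668 in XY clones mC3, mE6, mB4 and mG3. The median autosomal gene had a 129 share between 49.9% and 50% in every library. Each library is a single measurement of its clone, so values of single clones have no replicate error.

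The first question was whether monoallelic expression is more common in NPC clones than in ES cells. Most autosomal genes used both alleles in every library. In the NPC clones, 6.80% ± 0.736 (SD, n = 8) of testable autosomal genes were monoallelic, from 5.83% in mB4 to 8.37% in clone 129. In the ES lines the share was 5.49% ± 0.524 (SD, n = 2), with 5.87% (95% interval 5.45 to 6.30) in the XX line and 5.12% (4.74 to 5.53) in the XY line. The monoallelic calls of the ES lines leaned to 129, with 60.1% ± 1.16 (SD, n = 2) of the calls. In NPC clones 48.2% ± 2.16 (SD, n = 8) were for 129, a difference of -12.0 points (exact permutation p = 0.0444, the smallest possible). The difference in monoallelic share was 1.3 points and did not pass (exact permutation p = 0.0889). Among genes with at least 500 counts, 2.46% ± 0.446 (SD, n = 8) were monoallelic in NPC clones and 1.27% ± 0.0683 (SD, n = 2) in ES lines, a difference of 1.19 points (exact permutation p = 0.0444). Among the 10446 genes testable in all 10 libraries the difference was 0.166 points (exact permutation p = 0.889), and with counts thinned to the total of the XX ES line it was 0.715 points (exact permutation p = 0.222).

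**Figure D1:**
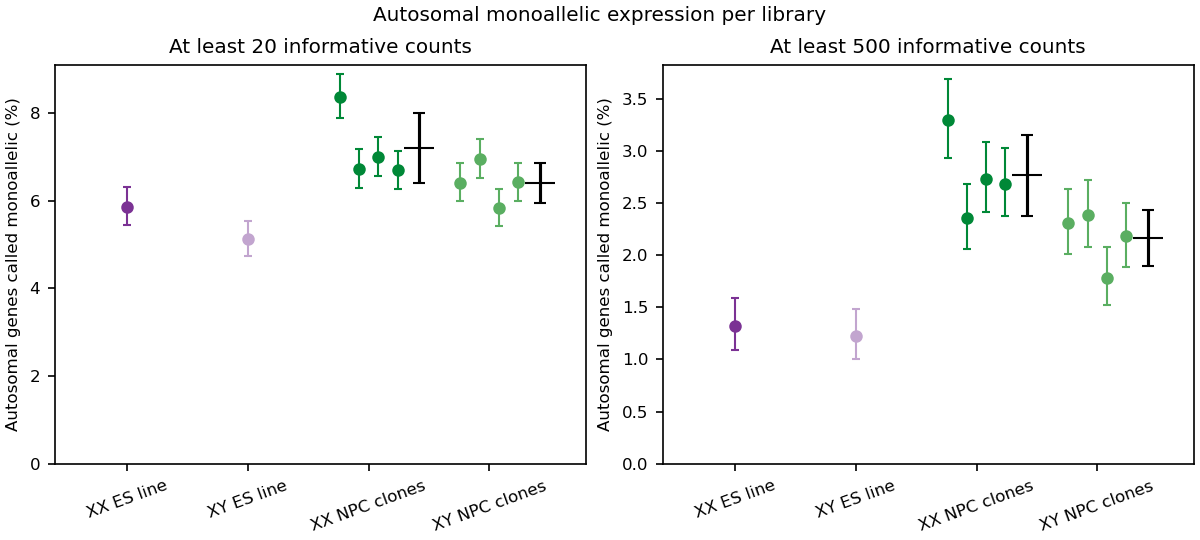
Percentage of testable autosomal genes called monoallelic in each library, grouped as ES lines, XX NPC clones and XY NPC clones. Separate panels show genes with at least 20 and with at least 500 counts. Coloured bars are exact 95% binomial intervals and black bars the mean ± SD of 4 clones. With at least 20 counts clone 129 is highest at 8.37% and the XY ES line lowest at 5.12%. With at least 500 counts they are at 3.29% and 1.22%.

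XX and XY NPC clones were compared to ask whether both lines give the same extent of monoallelic expression. The share was 7.20% ± 0.796 (SD, n = 4) in XX clones and 6.40% ± 0.457 (SD, n = 4) in XY clones. The difference of 0.794 points lay within the spread of the XX clones and did not pass (exact permutation p = 0.0857). Clone 129 carried much of it, since without that clone the difference was 0.402 points.

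The next question was which autosomal genes are monoallelic in some clones only. Of 12108 genes testable in at least 6 clones, 1653 (13.7%) were random monoallelic, and 218 of these used 129 alone in some clones and Cast alone in others. Cpped1, a calcineurin-like phosphoesterase (chromosome 16, 11803814 to 11909516), had a 129 share of 41.1% and 42.6% in the XX and XY ES lines. Its share was 99.9% in clone 129, 91.3% in E1.2, 0.0692% in G4 and 0.0409% in mG3, and 44.8% to 48.0% in the other 4 clones. Dis3l, an exonuclease of the cytoplasmic exosome (chromosome 9, 64154563 to 64189064), was expressed from 129 in clones 129 (98.8%), C2 (98.3%), mC3 (99.8%) and mG3 (99.9%). In E1.2 it came from Cast, with a 129 share of 0.139% (95% interval 0.0451 to 0.324). Plin2, which coats lipid droplets (chromosome 4, 86273107 to 86316012), had no 129 counts among 1466 in C2, which allows a share of up to 0.251% (exact 95% interval), and had a 129 share of 1.02% in G4 and 100% in E1.2. Plin2 had 0 counts in clone 129 and in mE6. Other genes with a large range were Lyplal1, Npl, Zfp422, Zfp612, Zfp286, Fggy, Rin3, Ptpmt1, 8430419L09Rik, A330040F15Rik and 1110021L09Rik. Among these genes the widest 95% interval of a clone was ± 19.2 points.

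Some random genes were members of the fixed lists. Ncan, which encodes the matrix proteoglycan neurocan, had a 129 share of 100.0% in clone 129 and 43.1% to 52.6% in the other 7 clones. Gja1, the gap junction protein connexin 43, had a 129 share of 100% in C2 and 48.8% to 53.4% in the other clones. Cd44, a hyaluronan receptor, was expressed from 129 in clones 129 (99.9%) and E1.2 (88.3%), and Ccnd1, cyclin D1, had a 129 share of 8.40% in G4. In mE6 the 129 share of Cdh20, a cadherin, was 0.221%, and Cdh20 had 0 counts in clone 129. Of the dominant disease genes, Bag3, a co-chaperone, came from Cast in clone 129 (129 share 0.276%) and from 129 in mE6 (99.6%), mB4 (99.7%) and E1.2 (93.7%). Tgfbr2, a receptor of TGF-beta, came from 129 in clone 129 (98.9%).

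Of the random genes, 842 were monoallelic in 1 clone, 373 in 2, 233 in 3 and the rest in 4 to 7. Of the 1184 testable in both ES lines, 713 (60.2%) were biallelic in both, and 256 of the random genes were monoallelic in at least 1 ES line. A further 122 genes used a fixed allele in every testable clone, 61 for each allele. Allele shares differed among clones for 2282 of the 12108 genes by the heterogeneity test, and 1016 of the random genes passed it as well. The number of random genes was lower under stricter limits, with 896 at a minimum of 100 counts and 484 at 500. It was 949 with a major allele of at least 95%, 621 with an FPKM of at least 1, and 1010 without clones G4 and E1.2.

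**Figure D2:**
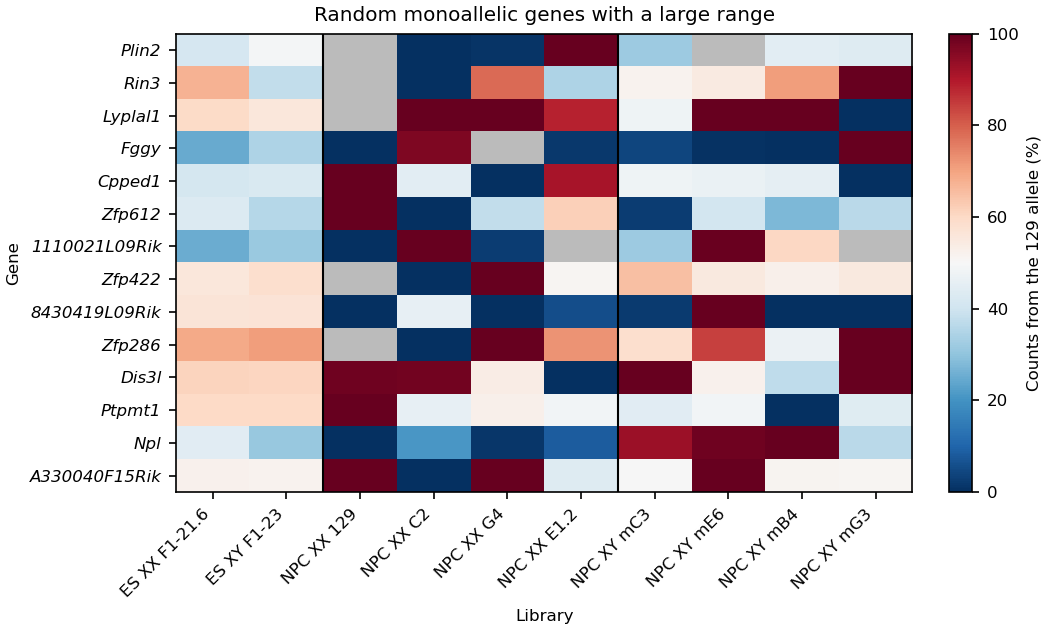
Heat map of the 129 share (percent of informative counts) in each library for 14 random monoallelic genes with a large range of shares among the clones; grey cells have under 20 counts. Cpped1 runs from 0.0409% in mG3 to 99.9% in clone 129 with both ES lines between 41.1% and 42.6%.

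The same genes tended to be monoallelic in both lines. Of 11826 genes compared, 1315 were monoallelic in at least 1 XX clone and 1134 in at least 1 XY clone, and 692 were so in both, where 126 fall by chance. The odds ratio was 25.3 (95% interval 21.8 to 29.3). Low counts make calls in both lines more frequent, so the genes were also split by mean count into 5 sets of like size. Odds ratios were 8.32, 28.1, 33.9, 60.7 and 49.6 from the lowest to the highest depth, with Fisher's exact p from 1.38e-99 to 1.52e-28. Only genes of fixed allele were left out, so genes skewed to the same strain's allele in both lines can add to the overlap. Their part was not tested. Fisher's test also takes genes as independent, which overlapping genes are not.

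The fixed lists were compared with all other genes, of which 13.5% to 13.7% were random. Imprinted genes stood out, with 17 of 33 random (51.5%, Fisher's exact test over 13 lists, adjusted p = 3.17e-06), against 12.1% in lists matched for depth (adjusted p = 0.0026). The rule also counts genes that differ between the lines, such as Peg3 and Snrpn, which used 1 allele mostly in XY clones. This share is therefore not one of random choice alone. Of the cadherins and protocadherins, which mediate cell adhesion, 7 of 31 were random (22.6%, adjusted p = 0.25; 7.62% in matched lists, adjusted p = 0.0407): Cdh11, Cdh20, Fat4, Pcdh8, Pcdh9, Pcdh17 and Pcdhb16. Of the astrocyte genes, 4 of 8 were random (Gja1, S100b, Clu and Aqp4; adjusted p = 0.0399; 9.30% in matched lists, adjusted p = 0.0273), but 1 of 5, Gja1, with at least 500 counts, and S100b and Aqp4 did not pass the heterogeneity test (adjusted p = 0.808 and 0.0560). The neuron list (4 of 7), the fibroblast list (4 of 8) and the hindbrain list (4 of 8) passed at an adjusted p of 0.0399 but not against matched lists (adjusted p = 0.234). Endoderm genes (3 of 6, adjusted p = 0.0799), pluripotency genes (2 of 6, adjusted p = 0.25), neural progenitor genes (5 of 30, adjusted p = 0.702), cell cycle genes (3 of 27, adjusted p = 1) and disease genes (11 of 73, adjusted p = 0.793) did not pass. None of 21 genes of DNA methylation and Polycomb and none of 18 housekeeping genes were random, which allows up to 16.1% and 18.5% (exact 95% intervals).

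Imprinted genes, which are expressed from the maternal or the paternal allele only, were compared between the lines. In the XY line the single X was 129, so 129 is its maternal genome; the direction of the XX cross is not known from the table. Imprinted genes were less imbalanced in XX clones, with a mean imbalance of 28.6% ± 5.18 (SD, n = 4), than in XY clones, with 44.7% ± 8.52 (SD, n = 4). The difference was -16.1 points, without overlap of the clones (exact permutation p = 0.0286, the smallest possible). Peg3, a paternally expressed zinc finger gene (chromosome 7, 6656608 to 6683163), had a 129 share of 45.7% to 51.6% in the XX clones. In XY clones mC3, mE6 and mG3 its share was 0.00853%, 0.0830% and 0.0156%, and in mB4 it was 51.9%. Snrpn, a paternally expressed splicing gene, had a 129 share from 0.0633% to 0.670% in the XY clones and of 0.0930% in clone 129, but of 42.1% to 46.3% in C2, G4 and E1.2. Mest, also paternally expressed, came from 129 in C2 (99.7%) and from Cast in mC3 (129 share 1.10%), mE6 (0.110%) and mG3 (0.132%), with both alleles in mB4 (51.8%). Impact came from Cast in mE6 alone (129 share 0.0248%), and Osbpl5 from Cast in G4 alone (129 share 4.00%).

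Among monoallelic imprinted genes, Cast was the allele of 11 of 13 in mC3, 14 of 16 in mE6, 8 of 9 in mB4 and 8 of 9 in mG3. In the XY ES line it was the allele of 5 of 13, and in XX clones 129, C2, G4 and E1.2 of 4 of 8, 1 of 4, 4 of 7 and 4 of 6. The ES lines, with 1 library each, showed an imbalance of 21.9% (XX) and 44.5% (XY). The maternally expressed RNAs H19, Meg3 and Rian had 129 shares of 89.2%, 95.1% and 94.6% in the XY ES line and 50.7%, 38.5% and 33.3% in the XX ES line. Other autosomal genes had a mean imbalance of 18.9% to 19.7% in the XY clones and 19.5% to 21.0% in the XX clones. The widest 95% interval of a share among these named genes was ± 14.8 points. With at least 50 counts the difference was -17.2 points but no longer passed (exact permutation p = 0.0571), and line and library set coincide here.

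**Figure D3:**
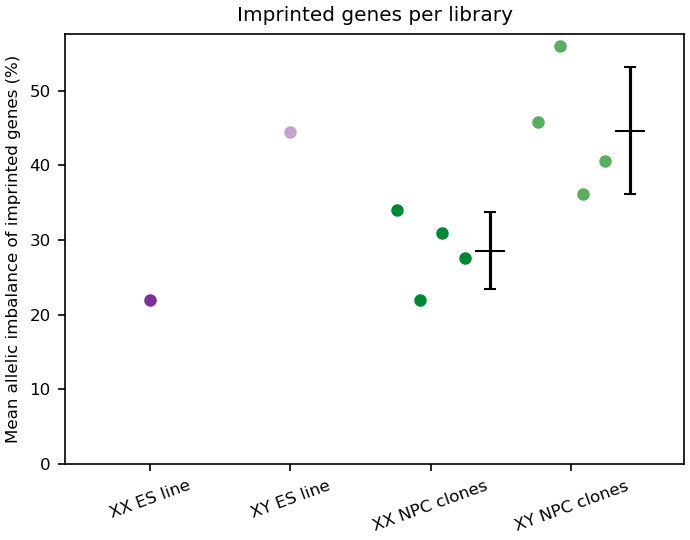
Mean imbalance of the imprinted genes (percent; 0 is equal alleles, 100 a single allele) per library, with black bars for the mean ± SD of 4 clones. XX clones lie between 21.9% and 34.0% and XY clones between 36.2% and 56.0%.

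**Figure D4:**
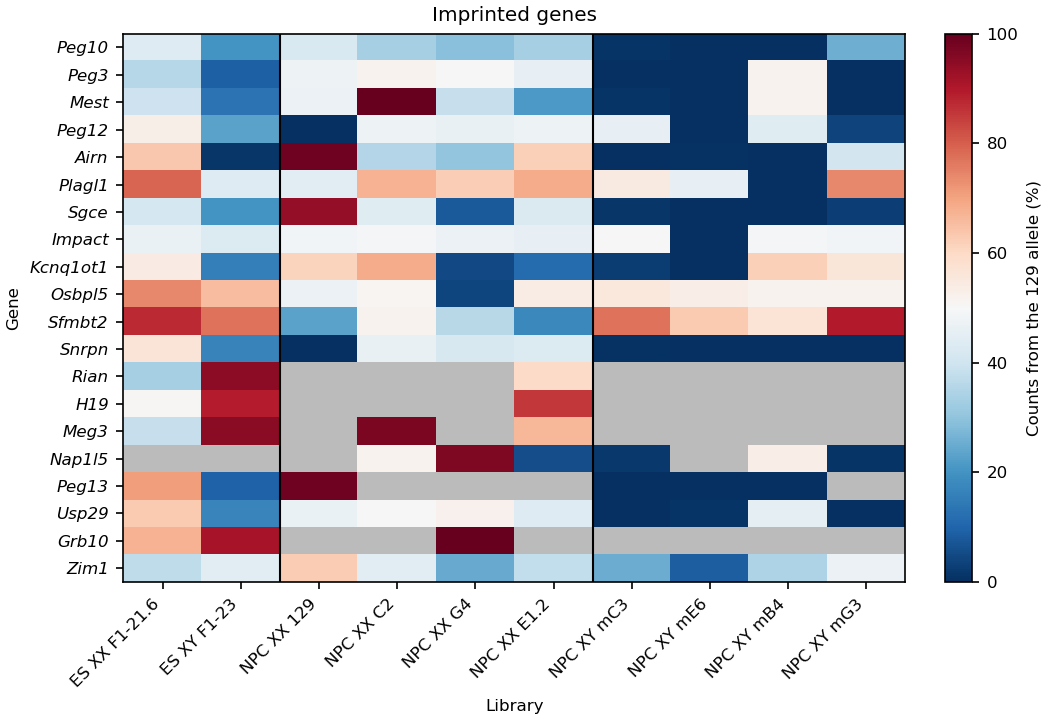
Heat map of the 129 share (percent of informative counts) of imprinted genes called monoallelic in at least 1 library; grey cells have under 20 counts. Peg3 is at 45.7% to 51.6% in the XX clones and at most 0.0830% in 3 of 4 XY clones, with mB4 at 51.9%.

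Alleles of X-linked genes were used to ask whether each XX clone had a single inactive X. The XX ES line expressed both X chromosomes, with 5.71% of X-linked genes monoallelic and a median major allele share of 55.6%. In the XX clones the median major allele share was 95.5% ± 5.48 (SD, n = 4), and 74.3% ± 10.7 of X-linked genes were monoallelic. Cast was the active X in clones 129, C2 and G4, and 129 in E1.2. Xist, the RNA that coats the inactive X (X, 100655712 to 100678572), came from the inactive allele in all 4 clones, with 99.9% of at least 184679 counts. In XY clones, which have a single X, 99.6% ± 0.120 (SD, n = 4) of X-linked genes were monoallelic, with a median minor allele share of 0%. Mid1 and G530011O06Rik (the latter chosen after its values were seen) were exceptions. In mC3, mE6, mB4 and mG3 the 129 share of Mid1 was 64.9%, 55.7%, 48.4% and 58.7%. That of G530011O06Rik was 47.0%, 19.1%, 11.4% and 22.1%.

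Reads from the inactive X differed between the clones. Among X-linked genes with at least 100 counts, the median share of the inactive allele was 0% in clone 129, 0.143% in C2, 6.62% in G4 and 11.5% in E1.2. The share of genes above 10% was 12.6%, 29.4%, 36.1% and 59.8% in the same order. Of 18 genes of the escape list other than Xist, 12 were above 10% in all 4 clones: for Kdm5c, a histone demethylase, the share ran from 37.9% in clone 129 to 46.2% in E1.2, and for Eif2s3x, a translation factor, from 39.6% in C2 to 47.1% in G4. Usp9x, a deubiquitinase, was at 6.36% in clone 129 but at 31.1%, 49.0% and 48.4% in C2, G4 and E1.2. Mid1 was at 0.929% in C2, but it also had Cast counts in the XY clones, whose single X was 129. Its share is therefore no clean measure of the inactive X. For 6720401G13Rik (Firre) the share ran from 0.592% in E1.2 to 39.8% in G4. A region at the start of the chromosome was raised in G4, with medians between 31.3% and 38.9% in the windows from 0 to 40 Mb, and in E1.2, with 34.9% to 40.9% from 0 to 30 Mb. In clone 129 the windows from 0 to 10 and 10 to 20 Mb were at 0.312% and 0.0943%, but the window from 20 to 30 Mb was at 26.6%. The window from 160 to 170 Mb was raised as well, at 25.6% in C2, 25.3% in G4 and 47.2% in E1.2. In C2 the windows from 0 to 10, 20 to 30 and 70 to 80 Mb were at 15.8%, 16.1% and 17.8%. Of 326 genes measured in all 4 clones, 32 were above 10% in each and 86 in none.

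**Figure D5:**
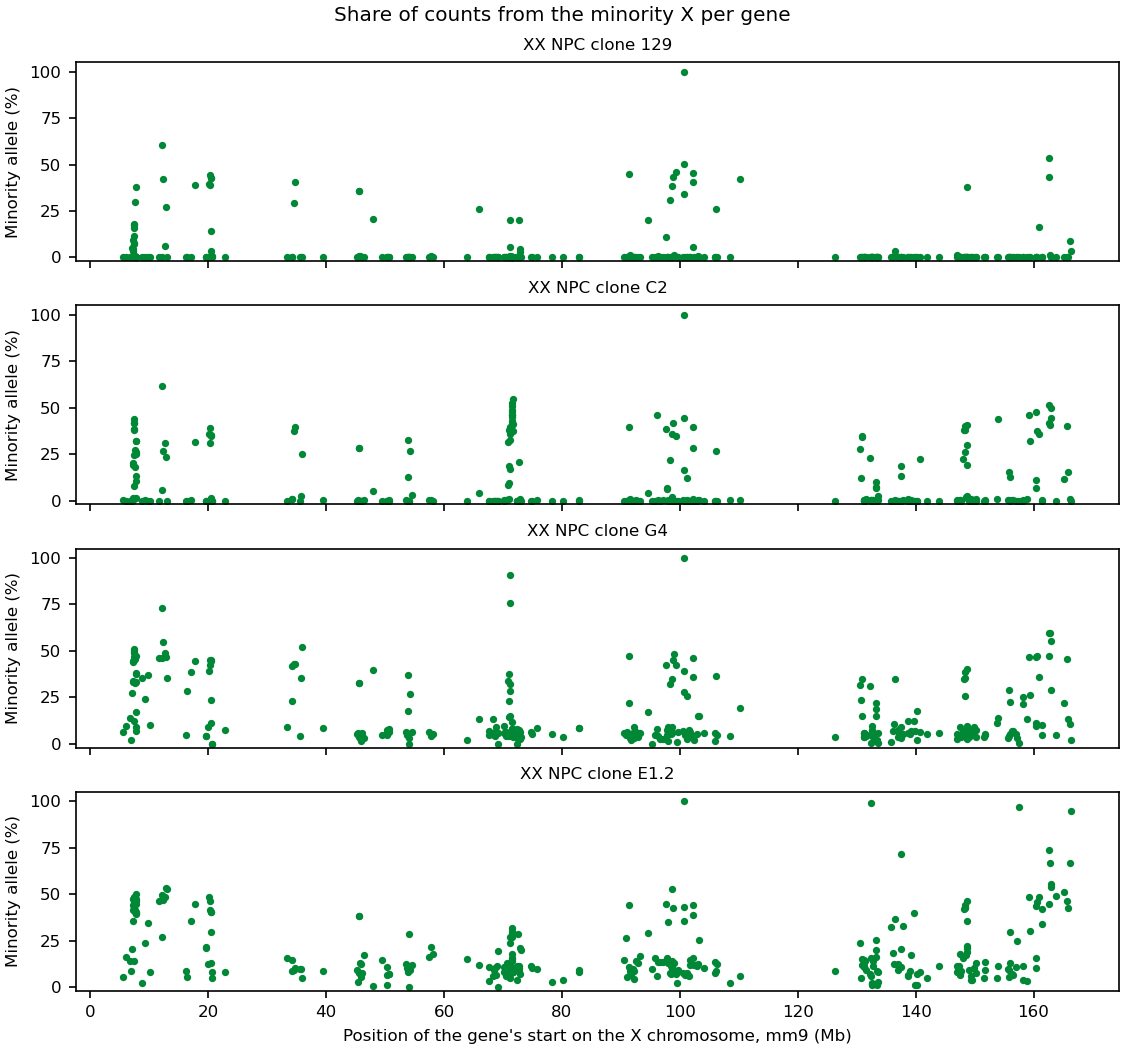
Share of counts from the inactive X (percent) of X-linked genes along the chromosome (Mb) in each XX NPC clone. Medians are 0% in clone 129, 0.143% in C2, 6.62% in G4 and 11.5% in E1.2; Xist lies at 99.9% in each clone.

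Expression of random monoallelic genes was compared between clones that used 1 allele and clones that used both. It was lower in monoallelic clones, with a median log2 difference of -0.25 (95% interval -0.28 to -0.21) over 1639 genes, and 75.8% of the genes were lower (sign-flip permutation p = 1e-05, the smallest possible). It was lower for 129-monoallelic clones (-0.22, 869 genes) and Cast-monoallelic clones (-0.29, 974 genes). With at least 500 counts in each clone used, the median was -0.60 over 591 genes, and in CPM it was -0.44. It was -0.16 with expression centred within each line and -0.56 with a pseudocount of 0.1. With a major allele of at least 95% it was -0.39. Taken by the clone that was monoallelic, the median ran from -0.089 in C2 to -0.39 in clone 129. Genes within a clone are not independent replicates.

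NPC clones were compared with ES lines to describe the change of cell type. Of 14561 genes, 9173 passed, 4851 higher and 4322 lower in NPC clones (9736 had an unadjusted p under 0.05). For 8527 of them the groups did not overlap, but they were selected by a test of the same difference, so this is no separate support. The share by chance, 0.0444, holds for genes that were not selected. Pluripotency genes fell together, with 10 of the 10 in the table lower (10 adjusted over the list alone), and the other 22 genes of the list are not in the table, which holds genes with counts in NPC clones. Esrrb, an orphan nuclear receptor of the ES state (chromosome 12), fell from 586 ± 80.5 CPM (SD, n = 2) to 2.44 ± 1.01 (SD, n = 8), a log2 change of -7.98 ± 0.34 (SE; edgeR adjusted p = 5.69e-07). Tcfcp2l1 changed by -11.64, Nr0b1 by -12.06 and Klf5 by -8.89. The camera test gave an adjusted p of 5.36e-10 over 17 lists, and adjusted p = 0.0206 with an estimated correlation.

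Genes of neural progenitors and radial glia rose: 25 of 31 were higher, 1 was lower (Prom1, chosen after its values were seen) and 5 did not pass (26 adjusted over the list alone; camera adjusted p = 9.09e-13, adjusted p = 0.0206 with an estimated correlation). Olig2, a transcription factor of ventral progenitors, was at 309 ± 37.2 CPM (SD, n = 8) in NPC clones and at 0 counts in both ES lines, at least 13035-fold higher. Fabp7, a fatty acid binding protein of radial glia, was at least 5672-fold higher. Bcan, the proteoglycan brevican, rose by 10.76 on the log2 scale, to 2650 CPM, and Olig1 by 10.59. Cadherins and protocadherins also rose, 30 of 33 (1 lower, 2 not passing; 32 adjusted over the list alone; camera adjusted p = 2.14e-10, adjusted p = 0.0525 with an estimated correlation). Pcdh10 was at least 827-fold and Pcdhb9 at least 687-fold higher. Cdh20 was at least 4439-fold higher on the mean, with 0 counts in clone 129 and with its call lost without the XX ES line (adjusted p = 0.0543) or the XY ES line (adjusted p = 0.0548), and Cdh1, the epithelial E-cadherin, fell by 12.31 on the log2 scale. Genes of hindbrain and spinal patterning rose in 10 of 16 cases, with none lower (10 adjusted over the list alone; camera adjusted p = 0.0124, adjusted p = 0.314 with an estimated correlation). Hoxa3 was at least 548-fold and Hoxd3 at least 99.2-fold higher.

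Of the DNA methylation and Polycomb genes, 14 of 21 fell, 3 rose and 4 did not pass (17 adjusted over the list alone; camera adjusted p = 7.72e-06, adjusted p = 0.104 with an estimated correlation). Cbx7, a Polycomb subunit of ES cells, fell by 5.82 on the log2 scale, the DNA methyltransferase Dnmt3b fell by 5.79 and the methylcytosine dioxygenase Tet1 fell by 3.52 on the log2 scale, while the Polycomb subunit Cbx8 rose by 4.44. Cell cycle genes were mixed, with 6 higher, 16 lower and 5 not passing of 27 (23 adjusted over the list alone; camera adjusted p = 0.0833). Those that rose include the D cyclins Ccnd2 (6.78 on the log2 scale) and Ccnd1 (3.44) and the inhibitors Cdkn2a (3.77) and Cdkn2b (3.46).

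Lists of other cell types did not pass camera. Fibroblast genes, a mark of feeder cells, fell in 7 of 16 cases with 9 not passing (7 adjusted over the list alone; adjusted p = 0.0725); Col1a1, a collagen, fell by 6.34 on the log2 scale, from 31.1 to 0.374 CPM. Among astrocyte genes 4 rose, 1 fell (Clu, chosen after its values were seen) and 4 did not pass (6 adjusted over the list alone; adjusted p = 0.368), with Sparcl1 higher by 11.07 on the log2 scale. Aqp4, S100b and Slc1a2 were also called, but not without the XX ES line (edgeR adjusted p = 0.157, 0.0603 and 0.0831). Neuron genes (3 higher, 4 lower and 8 not passing of 15; 7 adjusted over the list alone; adjusted p = 0.972; median -0.10, mean 1.02) included Mtap2 at 6.55. Oligodendrocyte genes (2 higher, 3 lower of 9; 5 adjusted over the list alone; adjusted p = 0.266) included Mobp at -6.99. Endoderm genes had 1 higher and 2 lower of 9 (3 adjusted over the list alone; adjusted p = 0.673), mesoderm genes 2 lower of 6 (2 adjusted over the list alone; adjusted p = 0.468), and forebrain genes 2 higher of 5 (1 adjusted over the list alone; adjusted p = 0.368). Lama1, a laminin, fell by 4.66, Eomes fell by 5.86, and Lhx2 rose by 8.02 on the log2 scale.

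Imprinted genes changed both ways, with 17 higher, 16 lower and 14 not passing of 47 (33 adjusted over the list alone; adjusted p = 0.66); the growth-restraining RNA H19 fell by 10.89 and Cobl fell by 11.12 on the log2 scale. Escape genes and the Xist locus had 5 higher and 7 lower of 19 (12 adjusted over the list alone; adjusted p = 0.538), and dominant disease genes 33 higher and 14 lower of 82 (47 adjusted over the list alone; adjusted p = 0.0833), with Zeb2 at least 87.0-fold higher. Of the housekeeping genes 3 rose, 7 fell and 9 did not pass (10 adjusted over the list alone; adjusted p = 0.547); Gapdh was 3.15 higher in counts but -1.02 and -0.79 in FPKM, so its direction depends on the unit. The largest changes outside the lists were an unnamed transcript fragment on chromosome 3 (88023011 to 88033884; at least 69412-fold higher), 2610017I09Rik (at least 5118-fold higher), Trh, the precursor of a releasing hormone (-13.47), and Morc1 (-13.11).

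XX clones were compared with XY clones to ask what differs between the 2 lines at the NPC stage, where line, sex chromosomes and library set coincide. Xist was at 2245 ± 407 CPM (SD, n = 4) in XX clones and 0.283 ± 0.116 (SD, n = 4) in XY clones, a log2 difference of 12.96 ± 0.43 (SE; edgeR adjusted p = 1.83e-05). The HoxB cluster (chromosome 11, 96108894 to 96215328), whose genes pattern the hindbrain and spinal cord, had 0 counts for all 8 of its genes in the table in every XY clone, and 6 of the 8 passed as higher in XX clones. Hoxb2 was at 21.4 ± 8.43 CPM (SD, n = 4) in XX clones, at least 2392-fold higher, Hoxb3 at least 1880-fold, Hoxb7 at least 4306-fold and Hoxb8 at least 3320-fold. The escape gene Ogt, a glycosyltransferase, was higher by 1.21 and Kdm5c by 0.51 on the log2 scale. In XX clones Ly6e, a membrane protein, was lower by a log2 value of -3.35 (16.2 against 164 CPM), the corepressor Tle4 by -1.34 and Cd44 by -0.78.

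Of 13591 genes, 175 passed, 119 higher and 56 lower in XX clones (3247 had an unadjusted p under 0.05). The groups did not overlap for all 175. These genes were selected by a test of the same difference, so this is no separate support. The share by chance, 0.0286, holds for genes that were not selected. X-linked genes passed more often, 24 of 438 (5.48%, 18 of them higher in XX clones) against 151 of 13153 autosomal genes (1.15%; Fisher's exact p = 1.98e-09). Escape genes and the Xist locus had 3 of 19 higher (6 adjusted over the list alone; camera adjusted p = 4.54e-05 over 16 lists, adjusted p = 0.0966 with an estimated correlation). Hindbrain and spinal genes had 3 of 14 higher, Hoxb2, Hoxb3 and Hoxb4 (9 adjusted over the list alone; adjusted p = 0.000498, adjusted p = 0.0997 with an estimated correlation). In the neural progenitor list 1 of 31 genes, Cd44, was lower (3 adjusted over the list alone; adjusted p = 0.0253, adjusted p = 0.582 with an estimated correlation). None of 27 cell cycle genes passed in edgeR (7 at an unadjusted p under 0.05, 3 adjusted over the list alone, 5 with DESeq2), while the list as a whole leaned lower in XX clones (median -0.30; adjusted p = 0.00166, adjusted p = 0.582 with an estimated correlation). Among disease genes 1 of 77 passed, the histone methyltransferase Mll2, higher by 0.72 (2 adjusted over the list alone; adjusted p = 0.558).

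The other lists had no gene past the threshold in edgeR and did not pass camera. These were pluripotency (9 genes; adjusted p = 0.337), neurons (12; adjusted p = 0.73; median -0.04, mean 0.14), astrocytes (9; adjusted p = 0.431), oligodendrocytes (6; adjusted p = 0.337), fibroblasts (13; adjusted p = 0.337), endoderm (7; adjusted p = 0.73), mesoderm (5; adjusted p = 0.73; median 0.92, mean -0.05), DNA methylation and Polycomb (21; adjusted p = 0.337), imprinted genes (36; adjusted p = 0.337), housekeeping genes (19; adjusted p = 0.229) and cadherins (32; adjusted p = 0.431). In the same order, 3, 3, 4, 2, 6, 2, 2, 8, 13, 6 and 6 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 1, 2, 3, 1, 2, 1, 1, 3, 8, 4 and 5. Adjusted over the list alone, 5 fibroblast, 3 DNA methylation and Polycomb, 3 housekeeping, 2 mesoderm and 1 astrocyte genes passed, and none of the other lists; the forebrain list, with 2 genes, was not tested. The number of genes depended on the clones used. Without clone 129 it rose to 496, with 172 of the 175 calls kept. It was 59 without C2, 20 without G4, 95 without E1.2, 11 without mC3, 8 without mE6, 7 without mB4 and 12 without mG3. DESeq2 called 1945 genes, and limma on FPKM called 373 and 401 with more genes lower than higher in XX clones (262 and 291 lower), where the median of all genes shifted from 0.01 to -0.10 and -0.09. Of the called genes named here, Xist, Hoxb2 and Hoxb3 passed without each clone in turn (highest adjusted p = 0.000592, 0.0446 and 0.0436). Each of the others lost its call without at least 1 clone. The highest edgeR adjusted p was 0.0511 for Hoxb7, 0.0670 for Hoxb4, Hoxb8 and Mll2, 0.0709 for Tle4 and 0.0845 for Ly6e. It was 0.128 for Ogt, 0.137 for Kdm5c and 0.142 for Cd44. Hoxb3 lost its call without both G4 and E1.2 (edgeR adjusted p = 0.0542). Cd44 also lost its call with no filter and without X-linked genes (edgeR adjusted p = 0.0537 and 0.0546).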

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

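The tests of Xist, of the evenness of the X-linked floor, of depth and of unit for the expression of monoallelic genes, and of the imprinted genes were chosen only after the results were seen.

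In XX clones G4 and E1.2, genes outside the raised regions of the X had a floor of reads from the inactive X, with a median of 5.94% and 10.6%, while C2 had 0.0824% and clone 129 had 0%. Cells with the other X inactive would bring Xist from the active allele, but at most 0.0880% of Xist counts did so in G4 and E1.2. Cells of another clone or genotype cannot be told apart from other sources: autosomal monoallelic genes with at least 500 counts had a median minor share of at least 0.777 of the floor, but in C2 that median was 5.23% without a floor. Of these genes, 19 of 178 in G4 and 20 of 170 in E1.2 had a minor share under 1%, which goes against such cells unless they share the allele or do not express the gene. A minority of cells without X inactivation cannot be told apart from other sources either. The interquartile range of the floor was at most 0.782 of its median, but the raised regions had been left out before it was taken; with them it was 2.67 and 1.42 times the median in G4 and E1.2. The 10 pluripotency genes had a median of 0.886% and 0.695% of the XX ES level in G4 and E1.2, below the 2.80% and 1.15% in clones 129 and C2, and since the clones form a single group no biological explanation was tested.

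Random monoallelic genes were expressed at a lower level in the clones that used 1 allele. If low counts had made the calls, the difference would lie near 0 at high depth, but it was -0.60 in log2 with at least 500 counts. Its larger size than the -0.25 of all genes is not read as an effect of depth. The pseudocount of 1 shrinks differences of genes with low FPKM, and with 0.1 all genes gave -0.56. The set of genes also changed, from 1639 to 591. If variants had been lost on the same allele in most genes, the difference would appear for that allele alone. The medians of 129-monoallelic and Cast-monoallelic clones differed by 0.073. Variants lost on 129 in some genes and on Cast in others could lower both medians, so this test cannot exclude them. The FPKM unit does not account for the lower level, since the median was -0.44 in CPM. A lower output from 1 allele than from both may be the biological explanation, as a hypothesis found and tested on the same data, and no group of the design tests it.

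Imprinted genes were less imbalanced in XX than in XY libraries. Variants misread at these loci in all libraries would leave XY clones at the level of other autosomal genes, but their imbalance was 2.32 times that level. In XX clones it was 1.44 times. Imprinted genes use 1 allele, so a high value in XY clones was foreseeable. It does not exclude misread variants as a cause of the lower value in XX clones. Feeder cells whose X reads as 129 do not account for the lower imbalance in clones 129 and C2, where the active X is Cast. A share of 23.9% and 51.0% of balanced cells would be needed to bring the mean of the XY clones to their imbalance, but the median share of inactive-X reads was 0% and 0.156% over all regions. A large share of feeder cells of pure 129 or Cast origin would also move the autosomal 129 share towards that strain. The median autosomal share ran from 49.96% in C2 to 50% in E1.2, with 49.9985% in G4. These values argue against such feeder cells in the XX clones. For feeder cells of hybrid or other origin the question stays open. The 13 tested fibroblast genes had a median log2 difference of 0.35 between XX and XY clones and did not pass (camera adjusted p = 0.337). The XX ES library, which shares its name prefix with the XY libraries, had 21.9% and lay below every XY library, but it is 1 library and cannot exclude a difference between library sets, so the sets and the lines cannot be told apart among the clones. A loss of imprints in the XX line, or another difference between lines or sex chromosomes, remains open and untested.

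The real division of the 8 clones into XX and XY gave 175 genes with different expression, and the highest of the other splits gave 3. Only 1 of 35 splits, the real one, gave as many. That is the smallest share that 35 splits allow, so the test makes chance less likely but cannot exclude it. The real split also follows the library prefixes.

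Several named genes had 1 clone far from the other 3 of its group, judged by the gap to the nearest other clone as a share of the range in log2 CPM; this was found in 9 of 166 groups of 4, where 8.3 are found by chance. Cdh20 was at -5.40 in XX clone 129 (0 counts), with the others between 6.25 and 7.60. Hoxa5 was at -0.23 in XX clone 129, with the others between 1.10 and 1.26. Ccnd1 was at 7.79 in G4, with the others between 9.18 and 9.41, and G4 was the clone in which Ccnd1 came from Cast. Slc1a2, a glutamate transporter of astrocytes, was at 10.32 in E1.2, with the others between 5.47 and 6.18. Pdgfrb was at 0.44 in E1.2, with the others between -5.40 and -4.89. The non-coding gene 2610017I09Rik was at 6.88 in E1.2, with the others between 6.49 and 6.55. Lhx2 was at 4.59 in XY clone mB4, with the others between 5.95 and 6.22. Dab2 was at 5.27 in mB4, with the others between 4.83 and 4.89. Hoxa3 was at 2.03 in mG3, with the others between 2.41 and 2.47.

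For 15 of 14848 genes the change from ES to NPC passed an interaction test of the lines (edgeR, adjusted p under the threshold; 1629 at an unadjusted p under 0.05). There is 1 ES library per line, assumed to vary like the NPC clones, which alone supply the spread, so a difference between single ES libraries is not excluded. The XY change minus the XX change was negative for 12 and positive for 3. For Xist it was -11.57, with a change of 8.59 in the XX line and -2.94 in the XY line. For Hoxb3 it was -20.77, a fitted value that is no bound because the XY clones had 0 counts. The others were Zfp608, Fam38b, Galr2, Frmd3, Jakmip2, Nfia, Fat3, Fzd2, Nav3, Gfra1, Klhl13, Slc6a8 and an unnamed fragment, chosen here after their values were seen.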

How the results depend on the processing

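Count minimums of 100 or 500, FPKM of at least 1, the beta-binomial test, limma on FPKM with a pseudocount of 1, CPM, the heterogeneity requirement, thinned counts for XX against XY, and leaving out the imprinted list, X-linked genes or clones G4 and E1.2 were chosen after seeing the data. So were all alternatives for the imprinted and list share results, and leaving out each XX clone for the X-linked share. Of 128 values of the allele comparisons under alternatives, 103 were labelled the same. They kept their direction and side of the threshold or stayed within their spread. Numbers of genes were judged by a loose ratio only, so 1171 and 2107 random genes counted as the same as 1653. Centred shares and the beta-binomial test each returned the same 1653 genes and odds ratio of 25.3, so they hardly vary the calls. Depth limits the allele comparisons, since a share of calls at 20 counts has wide intervals. The difference between NPC and ES lines depended on the settings. It passed (exact permutation p = 0.0444 each) with count minimums of 10 (1.51 points), 50 (1.42), 100 (1.41) and 500 (1.19), a major allele of 0.90 (1.28) or 0.95 (0.914), FPKM of at least 1 (1.01), and in genes with at least 500 counts in all 10 libraries (0.450). After thinning it was 0.715 points; that kept more of the 1.3 points than the bound set before the test, but the bound did not take in the spread, and the difference did not pass (exact permutation p = 0.222), so depth cannot be told apart from a difference between the cell types. With only the XY clones, of the same library set as the ES lines, it was 0.907 points (exact permutation p = 0.267), a design whose smallest possible p of 0.133 cannot pass. Without each library it ran from 0.933 to 1.68, and the XX and XY difference from 0.402 to 0.976. Causes were not tested where none is named.

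Random monoallelic genes numbered 896 and 484 at minimums of 100 and 500 counts, 949 at a major allele of 0.95, 621 with FPKM of at least 1, 1016 with the heterogeneity test as well and 1010 without G4 and E1.2, each a stricter filter or fewer clones; without each clone the range was 1286 to 1434. Of the 82 named random genes, 31 were random in every setting and 39 with at least 500 counts. Heterogeneity without overdispersion called 11309 genes, where it also made false calls on simulated data; without each clone it called 2008 to 2148. The odds ratio of the overlap was 24.1 to 29.7, the X-linked share 94.0% to 97.8% and the expression of monoallelic genes -0.31 to -0.20 without each clone. The imprinted difference was -17.2 points at 50 counts (exact permutation p = 0.0571; the cause was not tested), -16.7 without G4 and E1.2 (exact permutation p = 0.133) and -18.9 to -12.3 without each clone (exact permutation p = 0.0571); the last 2 are the smallest p those designs allow. Dominant disease genes were random in 6.45% at 500 counts.

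NPC against ES kept its size in every alternative (7857 to 9753 genes; 7032 to 9423 without each library; in a group left with 1 ES library that library is assumed to vary like the others). XX against XY gave 1945 genes with DESeq2, 373 and 401 with limma on FPKM (pseudocount 0.1 and 1; the cause was not tested), 23 without G4 and E1.2 (fewer clones), and 7 to 496 without each clone. With the estimated correlation, 7 of 33 list tests no longer passed. For NPC against ES these were hindbrain (adjusted p = 0.314), DNA methylation and Polycomb (0.104) and cadherins (0.0525). For XX against XY they were hindbrain (0.0997), escape (0.0966), neural progenitor (0.582) and cell cycle genes (0.582).

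Of 1269 values of genes named in NPC against ES, 31 (17 genes) no longer passed, most without 1 ES line, and Gapdh reversed with limma on FPKM (-1.02 and -0.79; the cause was not tested). Of 628 for XX against XY, 92 (15 genes) no longer passed, 8 (5 genes) newly passed and 33 (11 genes) reversed. None of the reversed genes was called as reported, but Pcdhga1 passed in the reversed direction with limma on FPKM (adjusted p = 0.0430 and 0.0385); in log2, and with the cause not tested, they were as follows. With limma on FPKM (pseudocount 0.1, then 1) Sparcl1 was at -0.57 and -0.55, Acta2 at 1.12 and 0.66, and Pcdhga1 at -1.78 and -1.24. Prrx1 was at 0.0090 with DESeq2 size factors, 0.0088 with DESeq2 and 0.0051 without a filter. Without G4 and E1.2, Mtap2 was at 0.0044, Sparcl1 at -1.40, Slc1a2 at -0.27, Dnmt1 at 0.060, Sdha at -0.10 and Pcdhga1 at -0.33. Without each clone in turn the ranges were Mtap2 -0.18 to 0.082, Sparcl1 -1.12 to 0.58, Slc1a2 -0.078 to 2.96, Ugt8a -2.13 to 0.61, Prrx1 -0.90 to 0.65, Sparc -0.21 to 0.070, Dlx1 -0.52 to 2.53, Sdha -0.10 to 0.19 and Pcdhga1 -0.15 to 0.38.

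Summing repeats with their clones and overdispersion from the pairs were not run, as the repeats were not analysed here. No autosome had a pooled 129 share above 60% or below 40%, so leaving such autosomes out removes nothing and tests nothing.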

Other observations

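The test of neighbouring genes was chosen only after the result was seen.

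Some genes used both alleles in both ES lines but the same single allele in every testable NPC clone, chosen here after their values were seen. Of 122 genes with a fixed allele in the clones, 74 were testable in both ES lines; 46 of these used the same allele in both ES lines and 9 were biallelic in both. Mt1, a metallothionein (chromosome 8, 96702989 to 96704227), had a 129 share of 40.3% and 34.7% in the XX and XY ES lines and of 98.6% to 100% in 8 clones. Hsf2bp (chromosome 17, 32081714 to 32171453) had 50.9% and 48.1% in the ES lines, from 11559 and 8068 counts, and 1.02% to 12.0% in the clones, from 73 to 276 counts. Cpne8 had 45.5% and 48.3% in the ES lines and 96.5% to 99.3% in 7 clones, and Abca8b, a transporter, 53.9% and 69.1% in the ES lines and 86.1% to 100% in 8 clones. Further genes were Trim17, which came from Cast in the clones, Tmem40 and Cybrd1, which came from 129, and a gene on chromosome 10 (21832856 to 21869076) without a symbol.

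Other Hox clusters had fewer called genes between XX and XY clones; the genes named here were chosen after their values were seen. In the HoxA cluster (chromosome 6) 2 of 8 tested genes, Hoxa6 and Hoxa10, were higher in XX clones, while Hoxa3 and Hoxa7 did not pass (edgeR adjusted p = 0.0517 and 0.0525). Like the HoxB genes, Hoxa9, which was not tested after the filter, and Hoxa10 had 0 counts in the XY clones, against 16781 and 3704 in the XX clones. The filter asks for counts in as many libraries as a group holds. Not every XX clone therefore reached its minimum for Hoxa9, and the sum does not stand for all XX clones. In the HoxD cluster (chromosome 2) none of the tested genes Hoxd3, Hoxd8 and Hoxd9 passed (edgeR adjusted p = 0.128, 0.624 and 0.590). The HoxC cluster (chromosome 15) had 5 genes in the table, all with 0 counts in the XY clones and at most 2.59 CPM on average in XX clones; the 1 tested gene, Hoxc8, did not pass (edgeR adjusted p = 0.0613).

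A hypothesis was that neighbouring genes share a monoallelic state. Without fragments and joined names, 181 pairs of random monoallelic genes lay within 100 kb of each other, and 126 pairs of calls fell in the same clone, against a median of 92 and a highest value of 116 in 10000 shuffles of the clones (permutation p = 0.0002, the smallest possible). In 64.3% of these the allele was the same, against 57.1% in the shuffles. Neighbouring genes may therefore share their state, although transcripts that overlap or run into each other could give the same count and were not tested.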
